A study of Homo sapiens with 24 samples.

How the data were processed

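ChIP-seq peak lists were analysed from UMUC1 bladder cancer cells that stably carried an empty vector (EV), wild-type UTX (WT) or mutant UTX (HEAA). There were 18 lists: 1 per line for UTX, MLL4, H3K27me3 and H3K4me1, and 2 per line for H3K27ac. The 6 input samples had no list and were not used here. Per the labels' protocols, cells were fixed with paraformaldehyde. Chromatin for UTX and MLL4 was digested with micrococcal nuclease and then sonicated, and chromatin for the histone marks was sonicated. Groups and replicate numbers were taken from the sample titles.

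MACS2 was named in the submitters' processing notes, with the builds hg19 and GRCh37, and its version is not given in the sources used here. The aligner, read filters and the handling of duplicates are not given in the sources used here either. The UTX and MLL4 lists were narrow peaks and the histone lists broad regions, as the deposited column layout shows. The fold enrichment of a peak over its background is a linear ratio that the authors' peak caller gave. The −log10 of the p-value and of the q-value were deposited for each peak, and all q values were at or below 0.05 in the narrow and 0.1 in the broad lists. The deposited score of a peak was 10 times its −log10 q, cut to a whole number, in nearly all peaks, and was not used. The peak names of the UTX lists hold a word for merging, and what was merged is not stated; the H3K27ac lists were called per library. Because peaks were already called, a site without a peak is one below the caller's threshold and not one without signal. Lists also lengthen with depth and antibody performance, neither of which can be read from the files, so the depth of every sample is unknown. Fold and q values are the authors' and were used only to describe, rank or filter peaks within a list.

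Intervals were read with chromosome names brought to one form and compared with custom code in Python 3.11.15 with NumPy 2.4.6 and pandas 2.3.3. Figures were drawn with matplotlib 3.10.9. Peaks overlapped when they shared at least 1 bp. Shares have 95% Wilson intervals, which cover counting error only. For overlap, the peaks were placed 1000 times at random, with their widths kept, inside the union of the H3K4me1 and H3K27ac regions (271 Mb). UTX sites were merged peaks called in both WT and HEAA and overlapping no EV peak. The H3K27ac comparison used control sites that were H3K4me1 regions called in all lines with no UTX or MLL4 peak within 1 kb, cut to 315 bp around their midpoint. The H3K4me1 and H3K27me3 comparisons used H3K27ac regions called in both EV libraries as control sites, with the same distance and width. Differences at UTX sites were set against 10000 random sets of control sites. These sets and the placements describe the lists and give no p-value, since peaks are not replicates.

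H3K27ac shares were compared over libraries with exact two-sided permutation tests, with 2 EV libraries against 4 and with 2 against 2. Neither design can reach 0.05. The labels do not say whether numbered libraries came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. H3K27ac regions of all libraries were merged, and their patterns of presence were counted for each of the 9 choices of 1 library of either number as the odd pair. The overlap code was tested on simulated data. Of 2000 simulated peaks with a planted overlap of 60%, 64.5% overlapped, which includes chance overlap, and without planted overlap the ratio to random placement was 1.003. All 77 planted gained regions were recovered.

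The text names regions by a rule fixed before the data were examined: the 15 UTX sites, 10 MLL4 sites, 15 gained and 15 lost H3K27ac regions with the best mean rank of fold over the lists that call them. Of the EV UTX peaks, the one with the highest fold and a pair on chromosome 3 were chosen after their values were seen. Positions are those of the lists, counted from 1. An annotation or sequence of the hg19 build was not used here, and the gene table at hand is on another assembly (GRCh38.p14). Sites were therefore not assigned to genes, and the planned comparisons of gene lists (luminal, basal, FGFR3 and MAPK, AP-1 and TEAD, mesenchymal, HOX, interferon, complex, housekeeping, blood, neuronal and endothelial genes), sequence motifs and promoters were not run. Alternatives covered the q threshold, the overlap rule, list length, peak-dense bins of 1 Mb, the random placement, the choice of sites and the replicates.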

Results

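The data were peak lists from chromatin immunoprecipitation sequencing (ChIP-seq) of UMUC1, an established human bladder cancer cell line. UTX, also called KDM6A, is a histone H3K27 demethylase and a subunit of the enhancer complexes built around the H3K4 methyltransferases MLL3 and MLL4. Each of 3 stable lines carried a puromycin-selectable pSIN construct. The EV line held the empty vector, the WT line wild-type UTX, and the HEAA line UTX with the substitutions H1146A and E1148A, which lie in its catalytic domain. Cells were harvested 3 days after plating. Of the 24 samples, 18 had a peak list and 6 were inputs. There was 1 list per line for UTX, MLL4, H3K27me3 and H3K4me1, and 2 numbered libraries per line for H3K27ac. Values from single lists have no replicate error. The read depth behind each list is unknown. Sites are named by their position on hg19.

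The first question was where UTX bound, with the empty-vector line as the background of the antibody. The UTX list held 31 peaks in EV, 2566 in WT and 2855 in HEAA. These covered 4.71 kb, 672 kb and 777 kb. The WT list was 82.8 times and the HEAA list 92.1 times as long as that of EV. Of the 31 EV peaks, 30 overlapped a WT peak and 30 overlapped a HEAA peak, and 2 overlapped an MLL4 peak of EV (6.45%, 95% Wilson interval 1.79% to 20.7%). The EV peak with the highest fold enrichment lay on chromosome 4 from 84128972 to 84129137 (9.94-fold). Chromosome 3 held 8 of the 31, including peaks at 193852300 to 193852396 and at 193852663 to 193852940. With a minimum −log10 q of 5, 9 EV peaks were left.

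The next question was whether the catalytic mutant occupied the sites of the wild-type protein. Of the 2566 WT peaks, 1727 overlapped a HEAA peak (67.3%, interval 65.5% to 69.1%). Of the 2855 HEAA peaks, 1723 overlapped a WT peak (60.4%, 58.5% to 62.1%). Random placements of the same peaks within H3K4me1 and H3K27ac regions gave an overlap of 0.552% and 0.490% of the peaks on average. The highest shares of peaks in any of 1000 placements were 1.05% and 0.876%. The overlap followed peak strength. In WT, 96.9% of the strongest 10% of peaks by q and 43.2% of the weakest 10% were in the HEAA list. In HEAA the corresponding shares found in WT were 97.5% and 34.6%.

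Merging the overlapping peaks and leaving out those that met an EV peak gave 1691 UTX sites, with a median width of 315 bp. The site ranked first by fold over both lists lay on chromosome 19 from 39524116 to 39524474 (12.8-fold in WT and 11.7-fold in HEAA). The next were on chromosome 12 from 53339284 to 53340008 (11.8 and 12.5), chromosome 17 from 53510455 to 53511010 (11.7 and 13.1), and chromosome 20 from 46110555 to 46110929 (12.7 and 11.4). Behind them came chromosome 12 from 123555177 to 123555478 (11.1 and 13.3), chromosome 3 from 37987458 to 37987853, and chromosome 9 from 90381661 to 90382013 (11.3 and 12.5). Among the 15 top-ranked sites, 12 had an MLL4 peak in WT and the same number in HEAA, and 3 had one in EV. H3K27ac was called in both libraries of every line at 13 of the 15. The other 2, on chromosome 21 from 45663850 to 45664174 and chromosome 6 from 71021803 to 71022181, had no H3K27ac region in any library and no MLL4 peak. The chromosome 21 site had H3K4me1 in all 3 lines, and the chromosome 6 site in none.

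**Figure D1:**
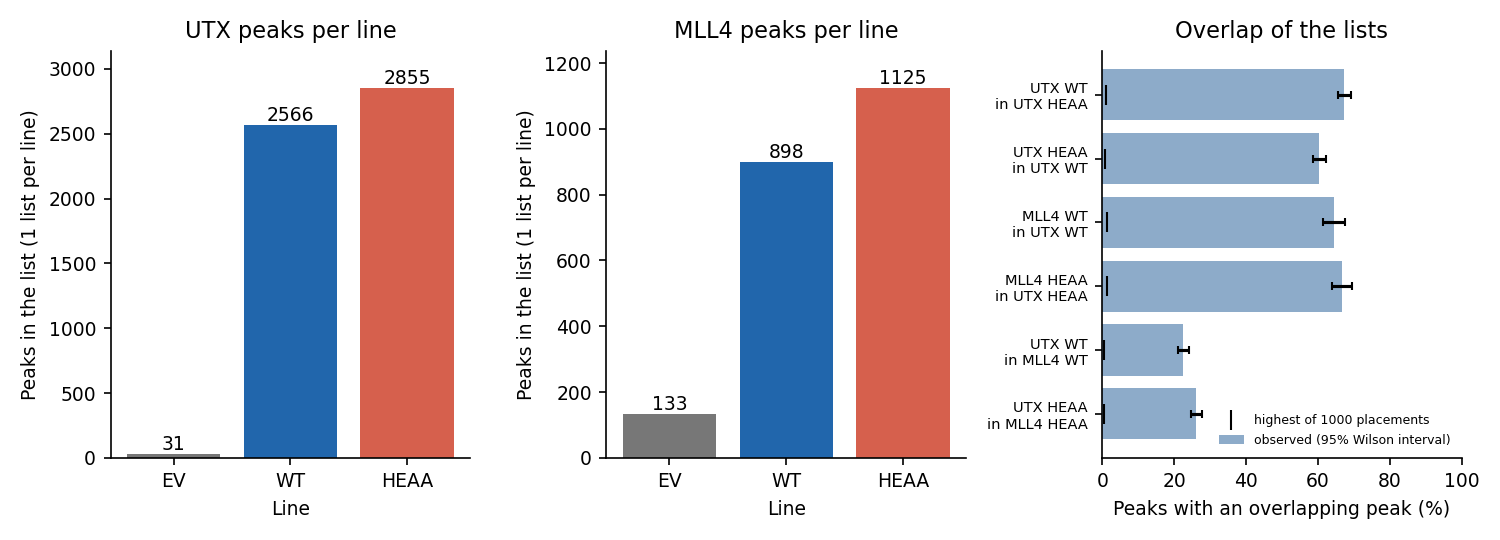
Bars show the number of peaks in the UTX and MLL4 lists of each line (left and middle) and the percentage of the peaks of one list that overlap a peak of another (right, with 95% Wilson intervals; vertical ticks mark the highest of 1000 random placements). UTX peaks number 31, 2566 and 2855 in EV, WT and HEAA, and MLL4 peaks 133, 898 and 1125.

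MLL4 was profiled to compare its occupancy with and without a UTX construct. The MLL4 list held 133 peaks in EV, 898 in WT and 1125 in HEAA, so that the 2 lines with a UTX construct had 6.75 and 8.46 times as many peaks as EV. Most MLL4 peaks of EV were also in the other lines, 101 of 133 in WT (75.9%, interval 68.0% to 82.4%) and 104 in HEAA (78.2%, 70.4% to 84.4%). WT and HEAA shared 466 peaks, 51.9% of the WT list (48.6% to 55.1%) and 41.4% of the HEAA list (38.6% to 44.3%). The highest shares among 1000 random placements were 0.891% and 0.622%. The MLL4 site ranked first by fold lay on chromosome 12 from 123555174 to 123555502 (14.0-fold in WT and 18.3-fold in HEAA) and had no MLL4 peak in EV. It coincided with a top-ranked UTX site. The second lay on chromosome 9 from 114932548 to 114932873 (10.5 and 14.4) and had an MLL4 peak in EV, as did the fourth, on chromosome 1 from 161053364 to 161053710 (13.2 and 10.4). The third, on chromosome 19 from 33789391 to 33789697 (10.1 and 11.3), did not. All of the 10 top-ranked MLL4 sites had a UTX peak in WT and in HEAA, and H3K27ac in both libraries of every line. Of these 10 sites, 5 had an MLL4 peak in EV.

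UTX and MLL4 belong to one complex, and their lists were set against each other within a line. MLL4 peaks mostly lay at UTX peaks, 580 of 898 in WT (64.6%, interval 61.4% to 67.6%) and 750 of 1125 in HEAA (66.7%, 63.9% to 69.4%). UTX peaks with an MLL4 peak were a minority, 579 of 2566 in WT (22.6%) and 747 of 2855 in HEAA (26.2%, interval 24.6% to 27.8%). Placements reached at most 0.429% and 0.595%. Both shares count nearly the same overlaps over lists of unlike length, so the contrast between them follows from the lengths of the lists. The share of UTX peaks with MLL4 was higher among the strongest UTX peaks by q. With the UTX list cut to as many of its strongest peaks as the MLL4 list held, it was 39.2% in WT and 42.2% in HEAA. Of the MLL4 peaks of EV, 45.1% lay at a UTX peak of WT and 47.4% at a UTX peak of HEAA, although only 1.50% lay at a UTX peak of EV. Of the 1691 UTX sites, 757 had an MLL4 peak in WT or HEAA and 934 had none.

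H3K27ac, a mark of active enhancers and promoters, was compared at the UTX sites with and without a UTX construct. UTX sites were acetylated in all 3 lines. The mean share with an H3K27ac region was 87.7% in EV (89.2% and 86.3% in replicates 1 and 2), 86.3% in WT (92.2% and 80.4%) and 84.9% in HEAA (93.4% and 76.3%; n = 2 each). The mean of the 4 WT and HEAA libraries lay −2.16 percentage points from that of EV (exact permutation test over 15 splits, two-sided p = 0.8, n = 2 and 4; smallest possible 0.0667). The difference had opposite signs in the 2 replicate numbers, +3.61 points in replicate 1 and −7.92 in replicate 2, so no direction held across libraries. Control sites with H3K4me1 in all lines and no UTX or MLL4 showed the same opposition. Their share was 33.1% ± 6.26 in EV (SD, n = 2) and 32.6% ± 15.7 in the 4 other libraries, with differences of +8.44 points in replicate 1 and −9.44 in replicate 2. The replicate numbers also separated the lists as a whole. From EV to WT to HEAA the regions covered 88.1, 96.0 and 111 Mb in replicate 1, and 71.7, 55.3 and 48.3 Mb in replicate 2. Sites with an MLL4 peak were acetylated more often (94.3% ± 3.08 in EV, n = 2) than sites without (82.4% ± 1.21, n = 2), and this order held in each of the 6 libraries.

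The comparison of WT with HEAA asked whether the catalytic residues mattered for acetylation at these sites. The difference was +1.42 points (exact permutation test over 3 splits, two-sided p = 1, n = 2 and 2; smallest possible 0.333). It was −1.18 points in replicate 1 and +4.02 in replicate 2. At the control sites the corresponding values were −6.12 and +3.76.

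**Figure D2:**
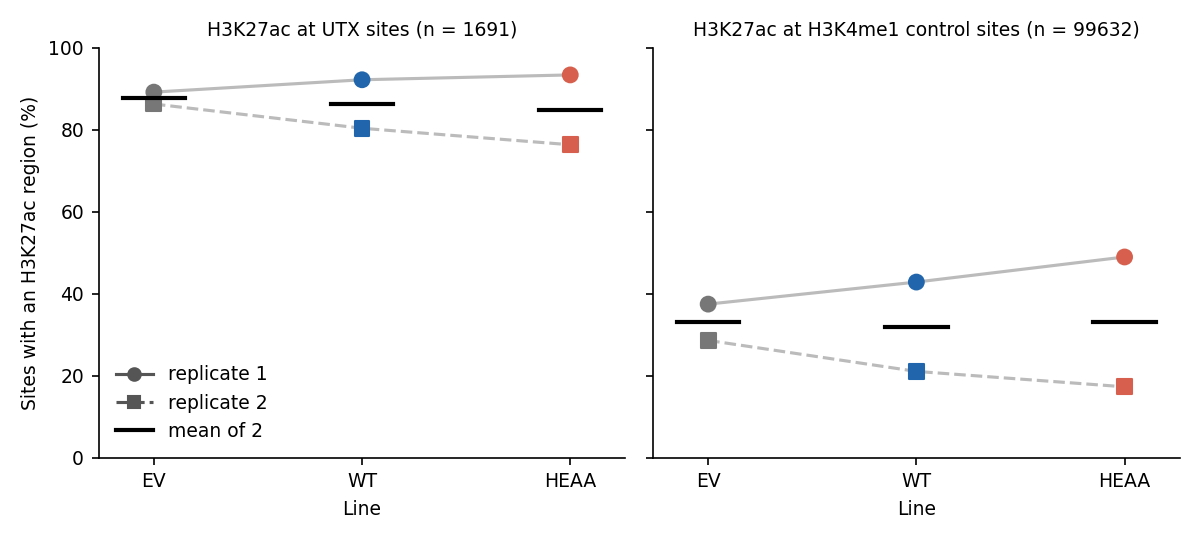
Points show the percentage of sites with an H3K27ac region in each library, by line and replicate number, at the 1691 UTX sites (left) and at 99632 control sites with H3K4me1 and no UTX or MLL4 (right); black bars are means of the 2 libraries. Replicate 1 lies above and replicate 2 below the mean in every line, and the WT and HEAA libraries deviate from EV in opposite directions in the 2 numbers.

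H3K4me1, the enhancer mark deposited by MLL3 and MLL4, was called at fewer UTX sites in the lines with a UTX construct. An H3K4me1 region overlapped 77.6% of the sites in EV (interval 75.5% to 79.5%), 66.9% in WT (64.7% to 69.1%) and 67.5% in HEAA (65.2% to 69.7%). The differences from EV were −10.6 points for WT and −10.1 points for HEAA. In WT, 274 sites had H3K4me1 in EV and not in WT, against 94 with the reverse. In HEAA these numbers were 274 and 103. Both lines shared 144 of the sites without the mark that had it in EV, and 47 sites had it in WT and HEAA and not in EV. At 36078 acetylated control sites without UTX or MLL4 the differences were −2.29 and −1.46 points. In 10000 random sets of 1691 such sites the values ranged from −4.55 to 0 for WT and from −3.90 to 0.946 for HEAA, so both observed values lay beyond every set. The difference was largest at the middle of the sites. At the midpoint 52.7% of the sites lay inside an H3K4me1 region in EV, 42.2% in WT and 42.5% in HEAA. At 0.5 kb from the midpoint these shares were 93.6%, 92.0% and 92.6%, at 1.5 kb 69.4%, 66.4% and 68.0%, and at 2 kb 54.1%, 54.7% and 55.7%. When a region within 1 kb counted, the differences were −0.118 and 0.177 points, but 99.7% of the sites in EV then had one, so a loss could hardly show. With 1 library per line these values describe the lists compared.

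The change in H3K4me1 was present at sites with and without MLL4. Sites with an MLL4 peak had H3K4me1 in 78.9% in EV, 66.3% in WT and 67.0% in HEAA, and sites without one in 76.6%, 67.5% and 67.9%. Among the 15 top-ranked UTX sites, 14 had H3K4me1 in EV, 11 in WT and 10 in HEAA. The chromosome 19 site from 12894588 to 12895126 had it in EV alone.

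**Figure D3:**
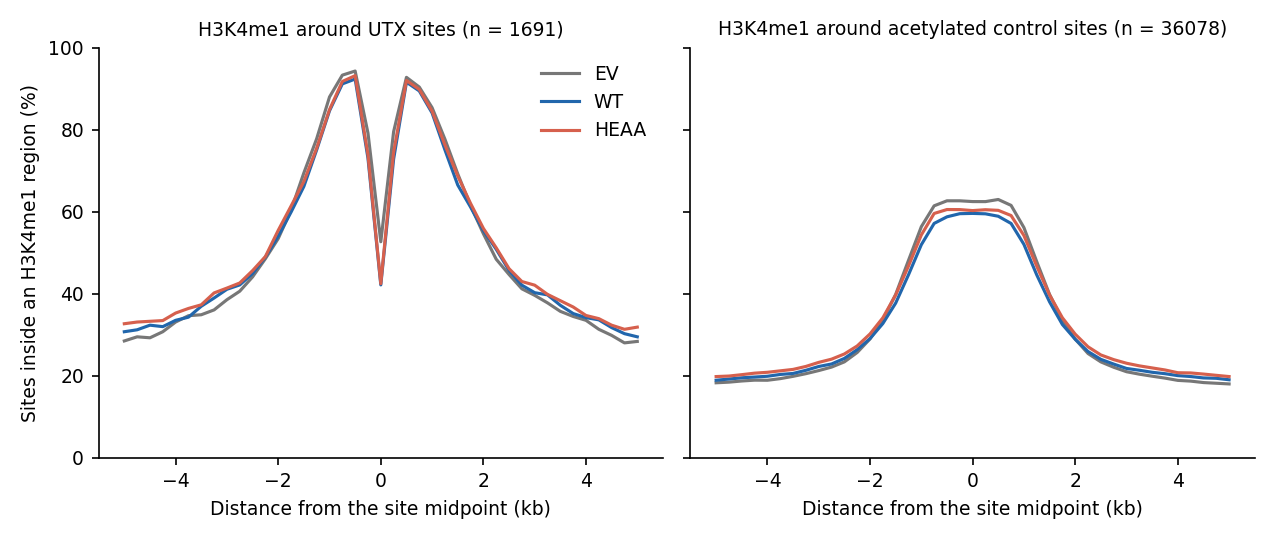
Lines show the percentage of sites lying inside an H3K4me1 region of each line at distances of up to 5 kb from the site midpoint, for the 1691 UTX sites (left) and 36078 acetylated control sites (right). At the UTX sites the lines dip at the midpoint, to 52.7% in EV, 42.2% in WT and 42.5% in HEAA, and differ by −1.57 (WT) and −0.946 (HEAA) points from EV at 0.5 kb.

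H3K27me3 is the repressive mark that UTX demethylates, and the HEAA line tests whether that activity leaves a trace at UTX sites. H3K27me3 was close to absent from UTX sites in every line. It was called at 4 of the 1691 sites in EV (0.237%, interval 0.0920% to 0.607%), at 2 in WT (0.118%, 0.0324% to 0.430%) and at 5 in HEAA (0.296%, 0.126% to 0.690%). The differences from EV, −0.118 and 0.0591 points, lay inside the range of 10000 random sets of control sites, which was −0.473 to 0.414 for WT and −0.296 to 0.473 for HEAA. With so few sites carrying the mark in EV, a loss at UTX sites was hardly measurable. With a minimum −log10 q of 5 the HEAA difference was −0.0740 points, so its sign turned, on 1 site with the mark in EV and 0 in HEAA. Within 1 kb, 26 sites had an H3K27me3 region in EV, 45 in WT and 47 in HEAA, differences of 1.12 and 1.24 points. These lay beyond every one of 10000 sets of control sites (−1.12 to 0.355 for WT and −1.06 to 0.651 for HEAA), whose own differences were −0.358 and −0.186 points. In EV, WT and HEAA, 25, 41 and 45 of these sites lacked an MLL4 peak. UTX peaks called in one line only had H3K27me3 within 1 kb at 14, 10 and 12 of the 839 WT peaks and at 8, 9 and 9 of the 1132 HEAA peaks. None of the 15 top-ranked UTX sites had H3K27me3 in any line.

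The H3K27ac lists were then searched for regions that set EV apart from both UTX lines. Among 81795 merged regions, 26030 were called in all 6 libraries. Another 442 were called in both WT and both HEAA libraries and in neither EV library, termed gained regions here, and 744 had the reverse pattern, termed lost regions. Of the 9 ways to choose one library of each replicate number as the odd pair, the EV pair gave the most regions of each kind, so each rank has a probability of 0.111 under exchangeable libraries. The WT pair gave 54 and 57, the HEAA pair 32 and 80, and the 6 mixed pairs 3 to 242 and 6 to 455. With a minimum −log10 q of 5 the numbers were 92 gained and 472 lost regions, and for gained regions another pair then reached 141. With equal-size H3K27ac lists they were 547 and 839, and the other pairs reached at most 161 and 133. A single replicate number alone gave 1457 and 9999 gained regions, and 11024 and 5598 lost regions, in replicates 2 and 1.

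The gained region ranked first by fold over the 4 libraries lay on chromosome 2 from 121153709 to 121158977, with 10.6- and 10.3-fold enrichment in WT and 9.66- and 10.3-fold in HEAA. It was the only one of the top 15 with a UTX peak, in both lines. A neighbouring pair on chromosome 20, from 51105796 to 51108034 and from 51108398 to 51111679, ranked second and seventh. Further gained regions lay on chromosome 18 from 19926562 to 19929612, chromosome 19 from 52301053 to 52305052, chromosome 4 from 102785259 to 102787769, chromosome 13 from 86082214 to 86088322, and chromosome 10 from 125046567 to 125048384. Chromosome 18 held 2 more of the top 15, from 8746907 to 8748394 and from 8799911 to 8801970. The region on chromosome 22 from 23266502 to 23272655 carried H3K27me3 in EV and in neither UTX line. H3K4me1 was present at 8 of these 15 regions in EV and at all 15 in WT and in HEAA. The lost regions were led by chromosome 8 from 32396365 to 32397739 (4.80- and 7.01-fold in EV), chromosome 16 from 88916081 to 88916538 (5.80 and 6.30) and chromosome 12 from 57583480 to 57583987 (6.22 and 5.97). None of these 3 had H3K4me1 in WT or HEAA. Of the top 15 lost regions, 15 had H3K4me1 in EV, 10 in WT and 11 in HEAA.

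Over all 442 gained regions, 27 carried H3K27me3 in EV (6.11%, interval 4.23% to 8.74%), and 5 carried it in WT and 5 in HEAA (1.13% each, 0.484% to 2.62%). H3K4me1 was present at 79.6% of the gained regions in EV (75.6% to 83.1%), 94.3% in WT and 94.8% in HEAA. Other regions called in 4 libraries, weighted to the same widths, had H3K27me3 in EV at 0.472% and H3K4me1 in EV at 95.9%. Gained regions were chosen for lacking H3K27ac in EV, which by itself can set these EV values apart. No conclusion is drawn from that comparison, and the differences between lines were not tested. A UTX site lay in 3 gained regions (0.679%, 0.231% to 1.98%) and in 0.680% of other regions called in 4 libraries, weighted to the same widths. For MLL4 peaks these values were 0 (upper bound 0.862%) and 0.917%, and for a UTX site within 10 kb 1.58% and 3.77%. All of the other regions had H3K27ac in at least 1 EV library, so the comparison is limited by the same selection. Among the 744 lost regions, 0 held a UTX site (upper bound 0.514%), against 0.142% of other regions called in 2 libraries, weighted to the same widths. A UTX site lay within 10 kb of 4.44% of the lost regions and 4.60% of those other regions. In the lost regions H3K4me1 was present at 88.6% in EV, 75.3% in WT and 81.6% in HEAA. H3K27me3 was present at 3 lost regions in EV (0.403%), 6 in WT (0.806%) and 12 in HEAA (1.61%), with the same limit from their selection.

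**Figure D4:**
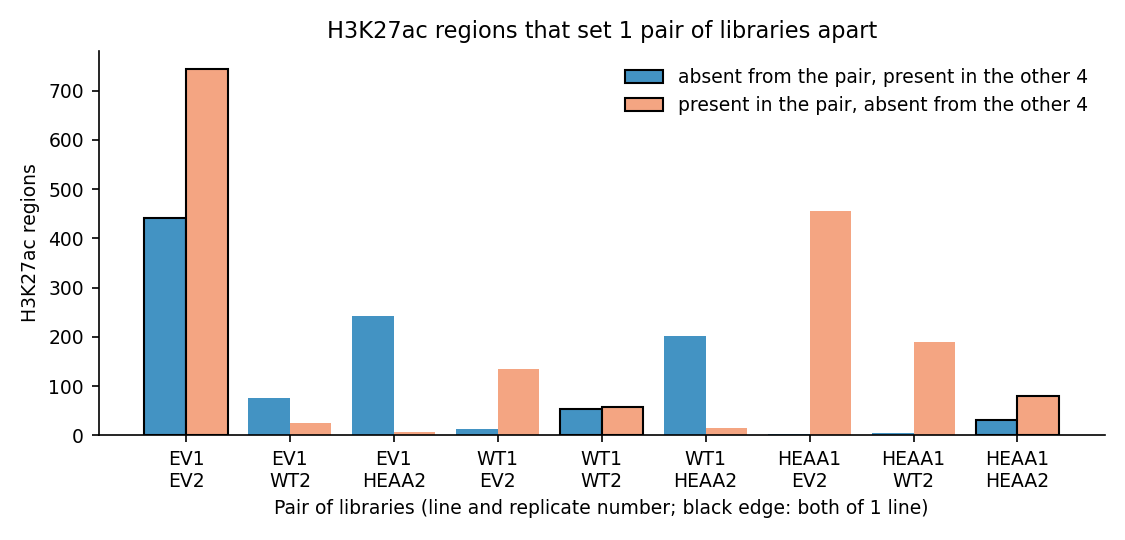
For each choice of 1 library of either replicate number as a pair, bars give the number of H3K27ac regions absent from the pair and called in the other 4 libraries (blue), and of regions with the reverse pattern (orange); black edges mark pairs from 1 line. The EV pair has 442 and 744, above the other 8 pairs, of which the highest have 242 and 455.

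H3K27me3 was also compared over the whole genome. Its regions covered 239 Mb in EV, 169 Mb in WT and 251 Mb in HEAA, from 231899, 199901 and 247498 regions. Coverage in WT was 0.704 times that of EV, and in HEAA 1.05 times. The ratio of WT to EV was below 1 on all 23 chromosomes examined, from 0.489 on chromosome X to 0.977 on chromosome 10. The ratio of HEAA to EV was above 1 on 15 chromosomes and ranged from 0.764 on chromosome 18 to 1.55 on chromosome 10. On each of the 23, the ratio of WT was below that of HEAA. Of the strongest 10% of EV regions by q, 84.0% met a region in WT and 89.7% in HEAA, and of the weakest 10% these shares were 26.3% and 39.8%. EV regions within 100 kb of a UTX site were kept less often than those over 1 Mb away, 45.0% against 48.7% in WT and 55.7% against 63.1% in HEAA. Regions between these distances were kept most often, at 53.5% in WT and 65.0% in HEAA, so the shares did not follow distance steadily. All of these shares were averaged over 10 equal groups of regions ranked by q. With a minimum −log10 q of 5, the regions left covered only 7.98 Mb in EV, 0.923 Mb in WT and 5.47 Mb in HEAA. The coverage ratio was then 0.116 for WT and 0.686 for HEAA, so the excess of HEAA over EV turned around. These strict ratios describe a small part of the regions. There was 1 list per line and no measure of depth.

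**Figure D5:**
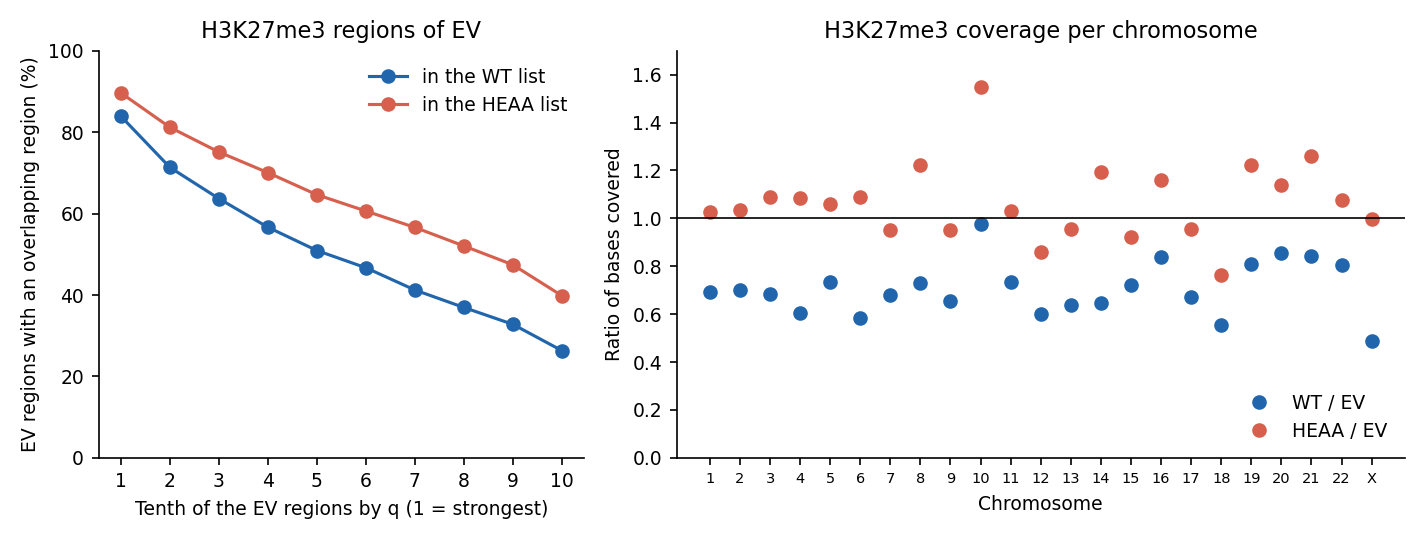
Left, the percentage of H3K27me3 regions of EV that overlap a region of the WT or HEAA list, for 10 equal groups of the EV regions ranked by q; right, the ratio of bases covered by H3K27me3 regions in WT or HEAA to those in EV on each chromosome. WT lies below HEAA in every group, from 84.0% against 89.7% in the strongest to 26.3% against 39.8% in the weakest, and on all 23 chromosomes.

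H3K4me1 regions covered 157 Mb in EV, 179 Mb in WT and 186 Mb in HEAA, 1.14 and 1.18 times the coverage of EV. Of the bases in the EV regions, 76.7% were also in those of WT and 79.7% in those of HEAA. The WT and HEAA lists shared 79.1% and 75.9% of their bases with each other. With a minimum −log10 q of 5 the ratios to EV were 0.816 and 0.943. That threshold kept 60.7 Mb in EV. With lists cut to the same number of strongest regions the ratios were 1.06 and 1.09. The greater coverage in the UTX lines was therefore absent only under the strict threshold.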

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

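Of the tests in this part, that of the empty-vector UTX peaks against the MLL4 list was chosen after the result was seen. H3K27me3 lay on opposite sides of EV in the 2 UTX lines. Bases covered differed by −70.7 Mb in WT and 12.1 Mb in HEAA, and the number of regions by −31998 and 15599. At UTX sites the share with H3K27me3 differed by −0.118 points in WT and 0.0591 points in HEAA, a matter of 4, 2 and 5 sites in EV, WT and HEAA. With a minimum −log10 q of 5 both lines lay below EV, at 0.116 and 0.686 times its coverage and at −0.0740 points each at UTX sites, the weight of 1 site. Within 1 kb of UTX sites both lines lay above EV, by 1.12 points in WT and 1.24 points in HEAA. These were 26 sites in EV, 45 in WT and 47 in HEAA. With 1 list per line, none of these differences was tested.

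The lower genome-wide coverage of H3K27me3 in WT goes the way that demethylation by UTX would take it. WT covered fewer bases than HEAA in the full lists (169 and 251 Mb) and under the strict threshold (0.923 and 5.47 Mb). The position of HEAA relative to EV depended on the threshold. HEAA covered 1.05 times the bases of EV in the full lists and 0.686 times under the strict one. Demethylation within 100 kb of the bound sites was predicted to widen the gap between HEAA and WT in EV regions kept, by over 5 points. The gap was instead smaller near UTX sites than over 1 Mb away (−3.78 points, near minus far), which goes against that prediction. Near regions were also kept less often in HEAA (55.7% against 63.1%). Near and far regions may therefore respond unlike to depth, so the test cannot exclude a local loss. A lower depth or enrichment of the WT library may account for the lower coverage in WT. In the strongest 10% of EV regions the kept shares differed by 5.72 points, just outside the 5 set before the test for this cause and far from the 20 set against it, so these cannot be told apart. A global activity of UTX away from its called sites remains open and untested.

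The UTX peaks of the empty-vector line mostly lay at strong sites of the UTX lines. The 27 matching WT peaks had a median percentile of 94.5 by fold within the WT list, with a range of 3.04 to 100. Residual UTX, or another protein that the antibody binds, at the same sites would give such a pattern. The EV peaks nonetheless differed from the 1691 UTX sites. In EV, 59.7% of them had H3K27ac against 87.7% of the sites (means of 2 libraries), and 48.4% had H3K4me1 against 77.6%. They were also narrower, with a median of 136 bp. The sites, at 315 bp, were merged from WT and HEAA peaks and so were widened, and wider intervals meet regions more easily. All WT UTX peaks, with a median of 234 bp, had H3K27ac in 84.8% and H3K4me1 in 70.7% in EV. With 31 EV peaks, the interval of their H3K4me1 share was 32.0% to 65.2%. Leaving out peak-dense bins of 1 Mb left 23 of the 31 EV peaks and 2326 of the 2566 WT peaks. Regions that any antibody pulls down are the alternative. Of the 31 peaks, 6.45% were in the MLL4 list of EV, with an interval that reaches 20.7%. Random placements gave 0.00645% on average. That list held only 133 peaks, so a low share in it cannot decide the question, which stays open.

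H3K4me1 was called at fewer UTX sites in both lines with a UTX construct. Lists that lose calls equally at all acetylated sites are argued against, since −10.6 points in WT and −10.1 points in HEAA lay beyond all 10000 sets of acetylated control sites. These sets cannot decide whether weaker lists lose calls mainly where the mark dips. In EV the control sites had no dip (62.5% at the midpoint and 62.8% at 0.5 kb), and the UTX sites had one (52.7% and 93.6%). A change that is largest at the centre describes the data better than an equal loss. The mean difference was −10.4 points at the midpoint, −2.16 points at 1 kb and 1.17 points at 2 kb. Broad regions that are bridged across the dip more readily in the EV list were not tested and remain open.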

How the results depend on the processing

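The placement inside constitutively acetylated regions and the control sites matched on H3K27ac width were chosen after seeing the data; all other alternatives were planned. Of 118 alternatives to the values that answer a comparison, 89 stayed within the stated margins: the interval of a share or of a difference between single lists, 1.5 times a count or ratio, or the direction of an H3K27ac difference. The 89 include H3K27ac differences that kept the sign of a mean on which the replicate numbers disagreed. They also include the replicate block, which leaves the difference unchanged by construction. The tally is therefore no measure of how firm the H3K27ac differences are. With a −log10 q of at least 5, UTX peaks in EV numbered 9, the share of WT UTX peaks in HEAA was 64.5% and that with MLL4 20.4%. H3K4me1 at UTX sites then differed by −16.7 points in WT and −14.1 in HEAA, with −9.78 and −5.89 at control sites, and H3K27me3 in HEAA by −0.0740, gained regions numbered 92 and lost regions 472. Coverage relative to EV was 0.116 in WT and 0.686 in HEAA for H3K27me3, and 0.816 and 0.943 for H3K4me1, the last 3 on the other side of 1. The cause was not tested. Equal-size lists gave UTX sharing of 63.5% of WT and 63.3% of HEAA peaks, MLL4 sharing of 46.0% of each, and UTX peaks with MLL4 of 39.2% and 42.2%. Only the longer list of each pair was cut, to its strongest peaks by q. With regions counted within 1 kb, H3K4me1, then at its ceiling (99.7% in EV), differed by −0.118 and 0.177 points and H3K27me3 by 1.12 and 1.24 points. With all HEAA peaks as sites, H3K4me1 in HEAA differed by −7.57 points. Leaving out a replicate number gave H3K27ac differences at UTX sites of −7.92 to 3.61 points between the UTX lines and EV and of −1.18 to 4.02 between WT and HEAA, 1457 to 9999 gained and 5598 to 11024 lost regions. Observed overlaps exceeded the mean of random placements at least 43.1 times for shared UTX peaks, 95.6 times for shared MLL4 peaks and 44.9 times for UTX with MLL4 under all 4 placements. H3K4me1 in WT and HEAA lay beyond all sets of control sites in 7 of 8 settings each, the exception being the 1 kb rule, and H3K27me3 in 2 of 7 each, the 1 kb rule and the strict q, the latter on 1 EV site against control sets of 0.

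With the replicate block, permuting line labels within a replicate number, the H3K27ac difference of −2.16 points between the UTX lines and EV had an exact permutation p of 0.667 (9 arrangements, smallest possible 0.111). That of 1.42 points between WT and HEAA had an exact permutation p of 1. No call existed to change. Deviations of same-numbered libraries from their line means correlated at 0.126 to 0.180 over regions. With 2 numbers these deviations mirror each other, so the correlation cannot decide whether the libraries were paired. Libraries of the same number and different lines shared 61.2% to 79.0% of their regions. The 2 libraries of a line shared 43.7% to 63.4%. Alternatives for gene lists, motifs and promoters were not run, for want of an hg19 annotation here. Unknown depth limits each comparison of list lengths.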

Other observations

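The measurements in this part were chosen after the main results were seen, and the clusters named are the largest. UTX sites lay in wide acetylated regions. Of the H3K27ac regions of EV replicate 1, 1475 held a UTX site, with a median width of 3597 bp against 976 bp for the others. The widest 5% of these regions, of at least 4324 bp, held 36.5% of the UTX sites and 22.2% of the acetylated bases. Most sites stood alone. Joined within 12.5 kb, 1444 sites were single and 247 (14.6%) fell into 120 clusters. The largest cluster held 4 sites on chromosome 15 from 70384334 to 70394227, with no MLL4 peak in any line. Clusters of 3 lay on chromosome 1 from 181081535 to 181088858 and from 201977352 to 201988109, chromosome 11 from 13161994 to 13165357, chromosome 2 from 219147437 to 219163136, and chromosome 20 from 30191928 to 30199774. For every 100 H3K27ac regions called in all 6 libraries there were 6.50 UTX sites, from 2.60 on chromosome X to 9.83 on chromosome 15.

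UTX peaks called in only one of the UTX lines were also acetylated in the empty-vector line. The 839 WT peaks without a HEAA peak had H3K27ac in 83.1% ± 5.14 in EV (SD, n = 2), and the 1132 HEAA peaks without a WT peak in 84.8% ± 3.69. MLL4 was rarer there. Of the WT peaks without a HEAA peak, 9.89% had an MLL4 peak in WT, and of the HEAA peaks without a WT peak 14.0% had one in HEAA. Both are below the 29.2% and 34.4% of the 1691 UTX sites with MLL4 in WT and in HEAA. The peaks of 1 line only were also weaker than the shared peaks. Their median −log10 q was 6.60 against 10.3 in WT and 6.14 against 10.1 in HEAA. They were narrower than the merged sites, with medians of 202 and 207 bp against 315 bp. Strength and width were not matched, so the lower shares cannot be tied to presence in 1 line.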
